A study of Homo sapiens with 28 samples.

How the data were processed

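Gene expression was measured on 28 Agilent 1-colour whole-genome arrays, 1 per RNA sample, in H9 human embryonic stem cells (hESC) and in HepaRG, a bipotent human liver progenitor line. Groups followed the labels: hESC labelled undifferentiated (3 arrays), hESC-derived hepatoblasts (hESC_HB, 5 arrays, day 10), hESC-derived cholangiocytes (hESC_Chol, 5 arrays, day 23), HepaRG hepatoblasts (HepaRG_HB, 4 arrays, day 4), HepaRG cholangiocytes (HepaRG_Chol, 4 arrays, day 10), HepaRG committed hepatocytes (HepaRG_cHep, 3 arrays, day 10) and HepaRG hepatocytes (HepaRG_Hep, 4 arrays, day 30). The series describes its replicates as separate experiments.

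Per the labels' protocols, Cy3-labelled cRNA was prepared from total RNA with a low-input 1-colour kit. Per the file headers, spots were quantified with Agilent Feature Extraction 10.7.1.1, while the submitters' processing notes name version 10.7.3.1. The deposited scanner files give each spot's processed signal, an intensity on a linear scale that is background-subtracted and detrended but not normalized between arrays, per the file headers. They also give the median pixel intensity of the spot and of its local background, and flags for outlier spots, saturation and spots well above background. The authors' deposited value table holds log2 values. Set against the scanner signals over 18437 probes, its columns matched log2 signals scaled to each array's 75th percentile and then centred per probe, with an SD of the difference of at most 0.0831 for 27 arrays. The scale and direction of that table were settled by this comparison, and the baseline used for its centring stayed unknown. Its column medians ran from -0.26 to 0.18.

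The scanner file of HepaRG_Hep replicate 3 was left out. Its header reports a failed grid, its spike-in slope was 0.554 against 0.948 to 1.02 on the other arrays, 64 spots were saturated and 10263 were marked as outliers. It differed from its own column of the authors' table by an SD of 2.66. The design fixed beforehand named all 28 arrays, so the use of 27 is a departure from it. The grid flag and these quality measures, not the comparisons' results, set the exclusion, but counts from 27 arrays had been seen before counts from 28 were made. Counts with all 28 files are given as an alternative. The alternative with the authors' values used all 28 columns of their table, that of HepaRG_Hep replicate 3 included.

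Each processed signal was divided by its array's 75th percentile over non-control spots, floored at 0.01 and taken to log2. The floor was set after negative signals had been seen, and 0.05 was run as an alternative. Outlier spots were set to missing, spots of one probe were averaged, and probes well above background on at least 3 arrays were kept (35007 probes). Of 42405 non-control probes, 25422 were named through their RefSeq accession in the reference table and 16983 had no name here. The brightest probe stood for each of 17566 genes. Among 4360 genes with several probes, probes called in opposite directions were found for 0 to 19 genes per comparison of groups and for 77 genes in the difference of the 2 cholangiocyte steps. No genome was used, so no coordinates are given.

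Group means of all 7 groups were fitted in limma 3.58.1 (R 4.3.3) with 20 residual degrees of freedom, and 6 comparisons of groups and 1 difference of differences were tested with lmFit and eBayes. All tests were two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with a change of at least 2-fold. A gene not well above background on any array of 1 group has only a bound. Its change is given as "at least N-fold", from the brighter group's mean against the dim group's mean of, per array, the higher of the lowest signal well above background and the gene's own value. No fold is given where that bound is under 1 or both groups were dim. The bound holds for the processed signal alone: the floor of 0.05, above the lowest signal well above background on each of the 27 arrays, and the normexp offset both raise dim groups, and for all 36 called named genes with a bound they gave a smaller fold than the bound, with 0 reversed. Values at the floor have no order. The number of arrays limits the precision of every value.

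The 29 gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison, with 212 missing values set to the group mean. Member counts were also made with p adjusted over the list alone. Camera with an estimated correlation and fry were alternatives. A list's estimated correlation comes from the fit of all 7 groups and is the same in every comparison. Arrays outside a comparison therefore enter its adjusted p. The lists covered biliary markers, hepatoblast and fetal liver markers, plasma proteins, drug metabolism, bile acids, liver transcription factors, amino acid and urea cycle enzymes, sugar metabolism, cholesterol synthesis, pluripotency, definitive endoderm, basement membrane and integrins, mesenchymal genes, epithelial junctions, Notch, TGF-beta, YAP and Wnt genes, primary cilium, cell cycle, interferon response, inflammation, hypoxia and glycolysis, and markers of endothelial, cardiac, neural, intestinal, pancreatic and blood cells. Groups, lists, main tests and 18 of the alternatives were fixed before the data were examined.

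Named genes followed a fixed rule with 3 parts. For the 2 cholangiocyte steps these were the 6 largest rises and falls among called genes whose groups did not overlap, up to 4 called members of each list, and a fixed set of biliary and hepatic genes whatever their result. The other comparisons used 4 and 3 in place of 6 and 4. For the difference of the steps the 5 largest in each direction were taken. Which of the rule's list members serve as examples was chosen after their values had been seen. SLC10A2, a member of the fixed set, had no probe among the genes tested. Some genes that this rule selects are not reported here.

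Slides and scans read from the file headers were treated as batches. All hESC-line arrays and HepaRG_Chol lay in scan 3 (slides 5 to 7), HepaRG_cHep and most of HepaRG_HB and HepaRG_Hep in scan 1 (slides 1 to 3), and replicate 4 of HepaRG_HB and of HepaRG_Hep in scan 2 (slide 4).

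The analysis code was tested on simulated data with known changes on 17566 genes. Of genes changed 8-fold, 95.5% were called for hESC_Chol against hESC_HB and 100% for HepaRG_Chol against HepaRG_HB. Of genes changed 3-fold, 98.5% and 92.5% were called, and of those changed 1.5-fold 1.49% were called in each. The share called of genes changed 3-fold was lower for HepaRG_Chol against HepaRG_cHep (82.1%) and for the difference of the cholangiocyte steps (76.1%). The runs for hESC_Chol against hESC_HB and HepaRG_Chol against HepaRG_HB had 2 and 6 false calls. The simulated noise was independent, with 1 spread per gene shared by all groups and no batch. In the arrays the median SD ran from 0.0904 in hESC_Chol to 0.361 in hESC, so these rates need not hold for them. That test was written after the arrays had first been fitted.

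Alternatives covered normalization (quantile, median), background correction (normexp, offset 50), the authors' values, filters, thresholds, probe choice, array weights, spread estimate, slide or replicate number as a block, and leaving out each array. Normexp had been planned on mean spot signals, which the files used do not give, so median signals were used. In all, 18 planned settings, 7 added after seeing the data and 27 that leave out 1 array were run. Python 3.11.15 and matplotlib 3.10.9 drew the figures.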

Results

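The data are mRNA levels on Agilent 1-colour arrays from 2 cell lines, H9 human embryonic stem cells (hESC) and HepaRG liver progenitors, sampled along differentiation to hepatoblasts and on to cholangiocytes, the epithelial cells of bile ducts, or hepatocytes. The groups held 3 hESC, 5 hESC_HB, 5 hESC_Chol, 4 HepaRG_HB, 4 HepaRG_Chol, 3 HepaRG_cHep and 3 usable HepaRG_Hep arrays. On these 27 arrays, 61.1% to 78.7% of spots were well above background, and the 75th percentile of the processed signal ran from 454 to 1506 intensity units. Levels are log2 signal relative to that percentile, changes are log2 fold changes with the standard error of the fit (SE), and 17566 genes were tested. The first principal component held 64.2% of the variance and separated the cell lines, and the second held 13.5%. The median SD of a gene between replicates ran from 0.0904 in hESC_Chol and 0.115 in HepaRG_Chol to 0.283 in HepaRG_HB and 0.361 in hESC.

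**Figure D1:**
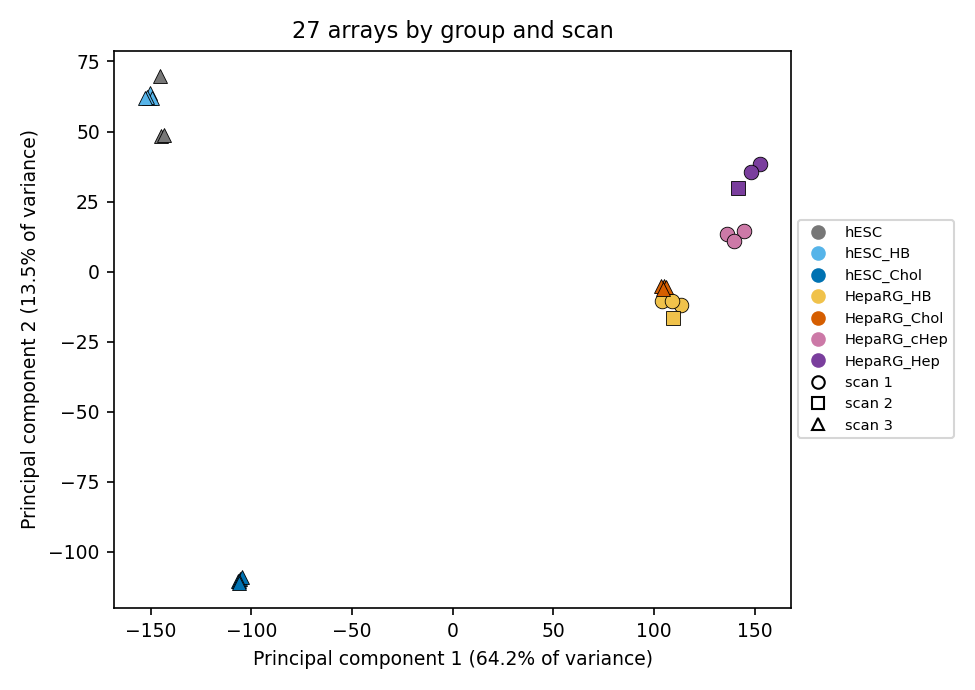
Scores of the 27 arrays on the first and second principal components, which hold 64.2% and 13.5% of the variance, with colour for group and symbol for scan. The components were taken over those of the 17566 genes that had no missing value. The hESC-line arrays lie at negative and the HepaRG arrays at positive values of the first component, and all 5 hESC_Chol arrays lie at the low end of the second.

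The first comparison asked how hESC_HB (5 arrays, day 10) differed from hESC (3 arrays), which are labelled undifferentiated. TTR, which encodes the plasma carrier transthyretin, was at least 942-fold higher in hESC_HB, and FOXA1, a pioneer factor of endoderm, at least 48.4-fold higher. FOXA2 rose by 5.57 (SE 0.779), GATA4 by 5.47 (SE 0.358) and KRT19, a keratin of ductal epithelium, by 2.78 (SE 0.174). POU5F1 and NANOG, core regulators of pluripotency, fell by 1.23 (SE 0.205) and fell by 2.44 (SE 0.124), yet POU5F1 still had a level of 6.57 ± 0.202 (SD, n = 5) in hESC_HB against 7.80 ± 0.128 (SD, n = 3) in hESC. AFP and SPP1 fell by 2.06 (SE 0.261) and fell by 4.71 (SE 0.250). The change of AFP was -1.28 with normexp background and -1.37 with a floor of 0.05. ALB, the gene of serum albumin, was not called and was above background on 4 of 5 hESC_HB arrays at a level of -5.89 ± 0.312 (SD, n = 5). HNF4A, KRT7, SOX9, AQP1, SCTR, GPBAR1 and SLC4A2 were not called either, with changes from -0.35 to 0.41, nor was SOX2 with -0.90. With the authors' values ALB (3.56) and HNF4A (2.06) were called, and SOX2 was called with array weights (-1.09) and after median scaling (-1.03).

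Among genes of cholesterol synthesis and uptake, 0 rose, 11 fell and 6 were not called (camera adjusted p = 1.1e-12, and adjusted p = 0.0243 with an estimated correlation). INSIG1 fell by 2.31 (SE 0.223). SQLE had a level of 3.94 in hESC and 1.94 in hESC_HB. In the pluripotency list 1 rose, 6 fell and 11 were not called (adjusted p = 3.5e-05, and adjusted p = 0.00307 with an estimated correlation). LEFTY1 fell by 4.78 (SE 0.396), while ZFP42 rose by 5.86 (SE 1.30). In the definitive endoderm list 8 rose, 2 fell and 3 were not called (adjusted p = 0.000178, but adjusted p = 0.450 with an estimated correlation), and SOX17 rose by 4.13 (SE 1.08). Of the plasma protein genes 10 rose and 15 were not called (adjusted p = 4.6e-05, but adjusted p = 0.450 with an estimated correlation), among them APOA2 with 6.30 (SE 0.552) and APOB with at least 33.1-fold. The liver transcription factors (6 rose, 1 fell, 8 were not called, adjusted p = 0.0105) and the hepatoblast list (7 rose, 2 fell, 9 were not called, adjusted p = 0.00395, with TBX3 at 5.90 and HHEX at 4.59) were called upward. The primary cilium list was too (5 rose, 15 were not called, adjusted p = 0.00747, with FOXJ1 at 2.35). With an estimated correlation these 3 lists had adjusted p = 0.192, adjusted p = 0.140 and adjusted p = 0.140. Hypoxia and glycolysis genes were called upward (4 rose, 1 fell, 9 were not called, adjusted p = 0.0357) and interferon genes downward (4 fell, 10 were not called, adjusted p = 0.0390), with adjusted p = 0.291 and adjusted p = 0.524 with an estimated correlation. With replicate number as a block neither was called (adjusted p = 0.0529 and 0.0944), nor was the interferon list after median scaling (adjusted p = 0.0691). For each of these 9 lists, counts adjusted over the list alone were the same. The largest rises beside TTR were those of GATA3-AS1 at 8.17 (SE 0.256), or 5.56 with normexp background, S100A14 at 7.92 (SE 0.414) and ALAS2 at 7.03 (SE 0.185). The largest falls were those of ABHD12B with -7.39 (SE 0.146), or -3.79 with the mean of its probes, ARMCX5 with at least 105-fold, LY6K with -6.39 (SE 0.472), or -3.82 with normexp background, and HHLA1 with -6.12 (SE 0.255).

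Of 17566 genes, 2501 were called between hESC_HB and hESC by limma, 1511 higher and 990 lower in hESC_HB. Within slide 6 the count was 2487, with slide as a block 2464. With all 28 files it was 1561, and INSIG1 (adjusted p = 0.132) and CFTR (adjusted p = 0.0800) were no longer called. CFTR rose by 2.07 (SE 0.254), which was 0.79 with normexp background and 0.74 with a floor of 0.05. hESC replicate 1 stood apart from replicates 2 and 3, with levels of 4.54, -5.59 and -5.79 for ZFP42, and levels at the floor, 2.19 and 1.86 for SOX17 and at the floor, 0.88 and 0.40 for EOMES, so replicates 2 and 3 had levels of endoderm genes that their label does not lead one to expect. Without hESC replicate 1 the count was 3223 and the changes were 9.27 for ZFP42, 1.24 for SOX17, 3.52 for FOXA2, 4.63 for GATA4, 3.72 for HHEX and -1.12 for SOX2, which was then called. The definitive endoderm list then had 8 risen and 4 fallen members, EOMES among the latter, and a median change of 1.24 in place of 3.18 (adjusted p = 0.00552, and adjusted p = 0.0363 with an estimated correlation). The interferon list was then not called (adjusted p = 0.203), the biliary and epithelial junction lists were called upward (adjusted p = 0.0340 and 0.0107, but adjusted p = 0.140 for both with an estimated correlation), and the cholesterol list was not called with an estimated correlation (adjusted p = 0.0828). With the spread estimated from only the arrays compared, SOX17 (adjusted p = 0.167) and ZFP42 (adjusted p = 0.105) were not called.

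The second comparison, named in the series design, was of hESC_Chol (day 23) against hESC_HB (day 10), with 5 arrays each. hESC_Chol had higher levels of SOX9, a transcription factor of bile duct development, by 4.40 (SE 0.171), of KRT7, a keratin of ductal cells, by 2.66 (SE 0.115), of AQP1, a water channel, by 3.37 (SE 0.186), and of SPP1, osteopontin, by 2.99 (SE 0.216). The change of AQP1 was 6.07 with the mean of its probes, 7.91 with normexp background and 8.77 with a floor of 0.05. In the last 2 settings the brightest probe was chosen anew. The main probe's hESC_HB values lay above that floor, so the larger change there came from another probe. The probes of AQP1 thus disagreed in size. The pluripotency regulators POU5F1 and SOX2 fell by 10.08 (SE 0.177) and fell by 7.33 (SE 0.162), and NANOG was at least 369-fold lower. The fetal liver gene AFP rose by 10.03 (SE 0.226) to 5.02 ± 0.0459 (SD, n = 5) and ALB by 8.36 (SE 0.187) to 2.47 ± 0.191 (SD, n = 5). Collagen genes of mesenchyme rose in the same arrays, COL3A1, near the floor in hESC_HB, by 8.99 (SE 0.398), or 6.47 with normexp background, and COL1A1 by 6.57 (SE 0.228). KRT19 was not called, with 8.08 ± 0.0707 (SD, n = 5) in hESC_HB and 7.84 ± 0.0269 (SD, n = 5) in hESC_Chol.

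Of the biliary markers 11 rose, 2 fell and 7 were not called (adjusted p = 0.00279, but adjusted p = 0.0557 with an estimated correlation). CLDN4 rose by 5.42 (SE 0.376) and CFTR, the chloride channel of bile duct epithelium, by 1.18 (SE 0.220). SSTR2 fell by 4.01 (SE 0.283). SLC4A2 with 0.54 (SE 0.203), GPBAR1 with 0.31 (SE 0.129), SCTR, the secretin receptor, with -0.07 (SE 0.366), and HNF4A with -0.28 (SE 0.143) were not called. In the hepatoblast and fetal liver list 8 rose, 6 fell and 4 were not called (adjusted p = 0.384), with H19 at 7.24 (SE 0.325) and IGF2 at 6.35 (SE 0.389). Of the plasma protein genes 18 rose, 1 fell and 6 were not called (adjusted p = 1.5e-09, but adjusted p = 0.182 with an estimated correlation). SERPINA1 rose by 8.85 (SE 0.189), FGG by 6.94 (SE 0.159) and FGB to at least 123-fold. The other hepatic lists were not called: drug metabolism (5 rose, 1 fell, adjusted p = 0.470), bile acids (4 rose, 3 fell, adjusted p = 0.900), liver transcription factors (3 rose, 4 fell, adjusted p = 0.878), amino acid and urea cycle enzymes (2 rose, 5 fell, adjusted p = 0.806), sugar metabolism (0 rose, 1 fell, adjusted p = 0.966) and cholesterol synthesis (2 rose, 1 fell, adjusted p = 0.470). In the pluripotency list 0 rose, 15 fell and 3 were not called (adjusted p = 2.3e-11, and adjusted p = 8.0e-06 with an estimated correlation), and PRDM14 was at least 39.2-fold lower. In the definitive endoderm list 0 rose, 9 fell and 4 were not called (adjusted p = 0.00290, but adjusted p = 0.508 with an estimated correlation). There EOMES was at least 67.2-fold lower, and GSC, KIT and SOX17 had changes of -5.13 (SE 0.620), -4.69 (SE 0.152) and -3.97 (SE 0.940). The estimated correlation of this list, 0.678, came from all groups, among them hESC with its replicate 1 apart.

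Of the mesenchymal and fibroblast genes 19 rose, 0 fell and 3 were not called (adjusted p = 3.8e-14, and adjusted p = 8.0e-06 with an estimated correlation), among them COL6A3 with at least 80.3-fold and DCN with 5.81 (SE 0.197), or 3.65 with the mean of its probes and 3.57 with normexp background. Of the TGF-beta response genes 11 rose and 2 were not called (adjusted p = 1.0e-09, and adjusted p = 0.000108 with an estimated correlation), with INHBA at 9.06 (SE 0.187) and TGFBI at 7.31 (SE 0.121). Of the basement membrane and integrin genes 15 rose and 3 were not called (adjusted p = 2.7e-10, and adjusted p = 0.00278 with an estimated correlation), with LAMB3 at 7.64 (SE 0.159), LAMA3 at 5.89 (SE 0.123), ITGA2 at 5.29 (SE 0.255) and ITGB6 at least 111-fold higher. Markers of cardiac muscle rose as well (5 rose, 1 fell, 2 were not called, adjusted p = 0.00223, and adjusted p = 0.0364 with an estimated correlation). NPPA, an atrial peptide, at the floor in hESC_HB, rose by 7.10 (SE 0.109) with that floor and by 4.66 with normexp background, the myosin genes MYH7 and MYH6 by 5.30 (SE 0.223) and 4.99 (SE 0.214), the latter 2.85 with normexp background, and TNNT2 by 4.20 (SE 0.260). The YAP targets (5 rose, 5 were not called, adjusted p = 0.0464, with CCN2 at 3.34 and AXL at 2.72), interferon genes (9 rose, 5 were not called, adjusted p = 0.000652, with IFI6 at 3.81 and IFIT3 at least 14.4-fold higher in processed signal, or at 2.04 with normexp background) and inflammation genes (10 rose, 7 were not called, adjusted p = 0.000408, with SERPINA3 at 7.54, CXCL1 at 5.79 and CCL2 at 5.37) were called upward. With an estimated correlation these had adjusted p = 0.438, adjusted p = 0.268 and adjusted p = 0.268. Cell cycle genes were called downward (13 fell, 10 were not called, adjusted p = 0.00743, but adjusted p = 0.683 with an estimated correlation), with TOP2A at -2.11 (SE 0.508), PLK1 at -1.94 (SE 0.376) and CDC20 at -1.75 (SE 0.256). The estimated correlation of that list, 0.636, also came from all groups, among them HepaRG_cHep, whose arrays disagreed on these genes. Hypoxia and glycolysis genes were also called downward (2 rose, 9 fell, 3 were not called, adjusted p = 0.00683, but adjusted p = 0.127 with an estimated correlation), with BNIP3 at -3.14, ADM at -2.35 and VEGFA at -2.31. In the Notch list 6 rose and 2 fell (adjusted p = 0.384), and JAG1 rose by 2.98 (SE 0.173), HES1 rose by 1.41 (SE 0.221) and DLL1 fell by 3.81 (SE 0.369). The lists of epithelial junctions (3 rose, 3 fell, adjusted p = 0.901), Wnt targets (5 rose, 2 fell, adjusted p = 0.450) and primary cilium (1 rose, 3 fell, adjusted p = 0.635) were not called. Nor were those of endothelial (2 rose, 3 fell, adjusted p = 0.966), neural (3 rose, 3 fell, adjusted p = 0.806), intestinal (2 rose, 0 fell, adjusted p = 0.246), pancreatic (2 rose, 0 fell, adjusted p = 0.116) and blood cells (0 rose, 1 fell, adjusted p = 0.923), although the intestinal factor CDX2 rose by 5.05 (SE 0.376). Counts adjusted over the list alone were the same for all 29 lists in hESC_Chol against hESC_HB.

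The largest rises in hESC_Chol beside AFP were those of CGA, a subunit of glycoprotein hormones, with at least 1682-fold, AREG with at least 1137-fold, TM4SF1 at 10.67 (SE 0.307), NNMT at 9.70 (SE 0.339) and UBD at 9.47 (SE 0.244). The largest falls beside POU5F1 and NANOG included those of ESRG with at least 1785-fold, ZSCAN10 with -8.28 (SE 0.128) and VRTN with -7.93 (SE 0.203). The hESC_Chol means of ZSCAN10 and VRTN and the hESC_HB mean of UBD lay at or near the floor, which sets these sizes, and with normexp background they were -5.79, -5.65 and 6.92. Of 17566 genes, 5028 were called by limma, 2291 higher and 2737 lower in hESC_Chol, and the groups also differed in day of culture. With slide as a block the count was 4967. Within slide 5, with 2 arrays of each group, it was 4576, and within slide 6, with 3 hESC_HB arrays and 1 hESC_Chol array, which is assumed to vary like the other arrays, it was 4176; the spread came from these and the other groups. Within slide 5 SOX17 (-3.86, limma adjusted p = 0.0924) and TOP2A (-2.23, limma adjusted p = 0.0726) were not called. Within slide 6 they were at -3.99 and -1.97 and again not called, nor were PLK1 (-1.90), HES1 (1.16) and CFTR (1.15). All these changes kept their direction. Few arrays are not the only limit here, since the spread also holds arrays outside this comparison. SOX17 ran from 3.24 to 3.35 in hESC_HB and from -0.88 to -0.56 in hESC_Chol. In hESC it lay at the floor, 2.19 and 1.86. The median SD of cell cycle genes was 0.121 in hESC_HB and 0.0603 in hESC_Chol, but 1.16 in HepaRG_cHep. CFTR was also not called with the authors' values (adjusted p = 0.0698), with all 28 files (adjusted p = 0.186) or with normexp background, where its change was 0.83. The YAP list was not called after quantile normalization (adjusted p = 0.0798) or with replicate number as a block (adjusted p = 0.0548).

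**Figure D2:**
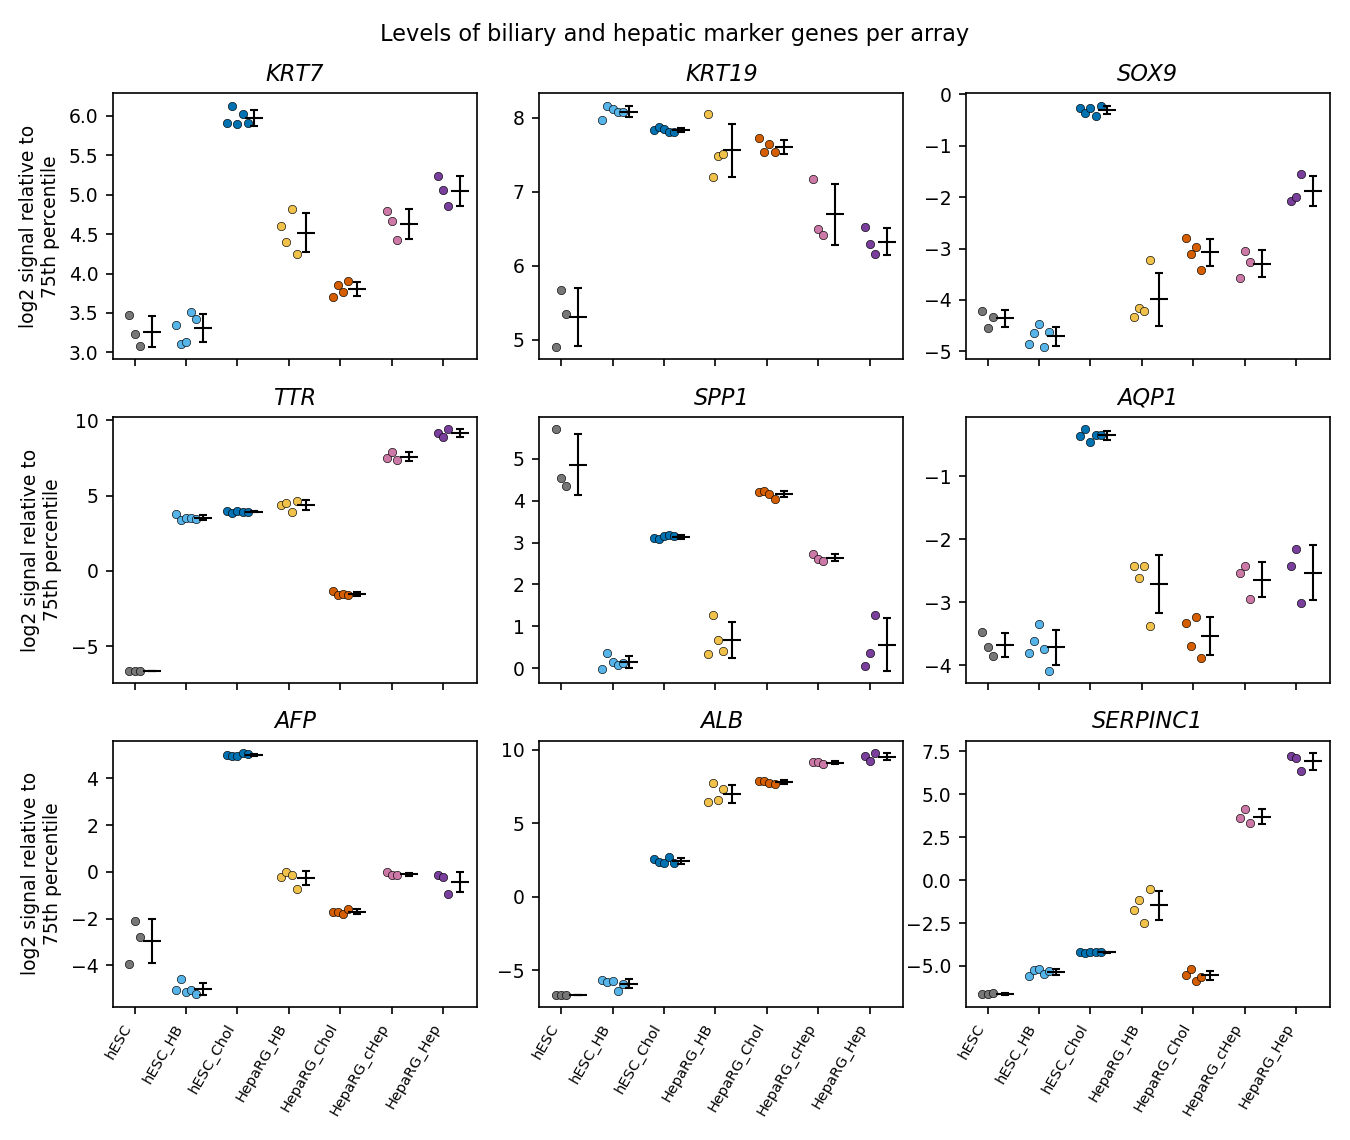
Log2 signal relative to the array's 75th percentile for 9 biliary and hepatic genes, one point per array, by group, with the mean and SD as a bar beside the points. hESC_Chol had the highest mean of KRT7 (5.97), SOX9 (-0.31), AQP1 (-0.35) and AFP (5.02), while KRT19 lay at 7.84 in hESC_Chol and 7.61 in HepaRG_Chol. AQP1 is shown for its main probe, and its probes disagreed in the size of the change.

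The third comparison, also named in the series design, was of HepaRG_Chol (day 10) against HepaRG_HB (day 4), with 4 arrays each. SPP1 rose by 3.47 (SE 0.242) and SLC4A2, the anion exchanger of bile duct cells, by 1.17 (SE 0.227) in HepaRG_Chol. The ductal genes KRT7 at -0.71 (SE 0.128), KRT19 at 0.05 (SE 0.168), SOX9 at 0.91 (SE 0.191), AQP1 at -0.83 (SE 0.208) and GPBAR1 at -0.64 (SE 0.145) were not called. The claudin gene CLDN2 rose by 5.76 (SE 0.173) and CDH1, E-cadherin, by 2.83 (SE 0.239). TTR fell by 5.91 (SE 0.144), from 4.38 ± 0.331 (SD, n = 4) to -1.53 ± 0.124 (SD, n = 4), and AFP fell by 1.44 (SE 0.253). ALB, at 7.03 ± 0.614 (SD, n = 4) in HepaRG_HB and 7.82 ± 0.107 (SD, n = 4) in HepaRG_Chol, was not called, nor was HNF4A. HNF4A was above background on no HepaRG_HB array, so its fitted change of 0.96 (SE 0.160), and its values under alternatives, are not measured sizes. CFTR and SCTR were not called and were above background on no HepaRG_HB array and on 3 and 1 of 4 HepaRG_Chol arrays.

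Of the YAP targets 0 rose, 8 fell and 2 were not called (adjusted p = 0.000123, but adjusted p = 0.198 with an estimated correlation), with ANKRD1 at -2.88 (SE 0.231) and CCN2 at -2.31 (SE 0.362). Of the liver transcription factors 5 rose and 10 were not called (adjusted p = 0.00244, but adjusted p = 0.198 with an estimated correlation), with NR5A2 at 2.27 (SE 0.269), or 1.11 with the mean of its probes, CEBPA at 2.15 (SE 0.116), NR1H4 at 1.88 (SE 0.233) and FOXA1 at 1.87 (SE 0.211). No other list was called, but with normexp background the basement membrane and interferon lists were called upward (adjusted p = 0.0279 for both). Of the biliary markers 6 rose, 2 fell and 12 were not called (adjusted p = 0.789), with ELF3 at 1.85 (SE 0.301) and CLDN4 at a level of -2.07 against -3.57 in HepaRG_HB. Of the plasma protein genes 5 rose, 8 fell and 12 were not called (adjusted p = 0.525), with SERPINC1 at -4.08 (SE 0.275), RBP4 at -3.02 (SE 0.188) and F2 at -2.65 (SE 0.241). In the bile acid list 5 rose, 3 fell and 13 were not called (adjusted p = 0.620), with NR0B2 at 3.62 (SE 0.308) and SLC51B at 3.03 (SE 0.270). With normexp background these 2 genes were at 1.36 and 1.41. In the drug metabolism list 6 rose, 2 fell and 11 were not called (adjusted p = 0.757), with ADH4 at 4.61 (SE 0.333) and UGT2B4 at -2.96 (SE 0.345). In the hepatoblast list 3 rose and 2 fell (adjusted p = 0.731), with NCAM1 at 2.45 (SE 0.303) and H19 at -3.60 (SE 0.363). Of the basement membrane and integrin genes 5 rose and 3 fell (adjusted p = 0.355), with ITGA2 at 2.77 (SE 0.285), LAMB3 at 2.75 (SE 0.178) and COL4A2 at -2.24 (SE 0.107). Of the mesenchymal genes 3 rose and 6 fell (adjusted p = 0.721), with S100A4 at 3.34, POSTN at -2.97 and TAGLN at -2.80. Of the epithelial junction genes 5 rose and 2 fell (adjusted p = 0.292), with CLDN3 at 2.32 and CGN at 1.95. With normexp background CLDN3 was at 1.35, SERPINC1 at -2.47 and UGT2B4 at -1.65. Cell cycle genes were mostly not called (0 rose, 2 fell, adjusted p = 0.525), and 1 fell when adjusted over the list alone. For the other lists named here, counts adjusted over the list alone were the same.

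The largest rises beside CLDN2 were those of ACOX2 at 5.36 (SE 0.298), CREB3L3 at 5.26 (SE 0.352), RGS4 at 4.94 (SE 0.240), or 2.03 with normexp background, and NIBAN1 at 4.76 (SE 0.244), with NTS at least 13.1-fold higher. The largest falls beside TTR were those of AMTN with at least 95.0-fold, CNN1 with -5.86 (SE 0.296), KRT5 with -5.84 (SE 0.244), CEMIP with -4.82 (SE 0.154) and NDN with at least 19.6-fold. With normexp background CNN1 was at -4.15, KRT5 at -3.66 and CEMIP at -2.88. Of 17566 genes, limma called 3059, 1656 higher and 1403 lower in HepaRG_Chol. The share of called genes that were higher was 54.1%, or 64.8% after quantile normalization and 45.3% with normexp background, so the direction of the majority depends on the choice. All HepaRG_Chol arrays were in scan 3 and all HepaRG_HB arrays in scans 1 and 2, so batch and group cannot be told apart here. Spike-in RNAs, added in equal amounts, had a mean shift of -2.10 in HepaRG_Chol over 10 probes. With normexp background the count was 1647, and CLDN4 at 0.77 and ITGA2 at 0.73 were not called; CLDN4 was also not called with all 28 files (adjusted p = 0.0511). SOX9 (adjusted p = 0.000392), ALB (1.13) and HNF4A (1.12) were called after quantile normalization, SOX9 also with array weights (1.15), HNF4A after median scaling (adjusted p = 4.8e-06), and SOX9 (1.00), HNF4A (1.42) and SCTR (1.29) with the authors' values. Leaving out single arrays called SOX9 without HepaRG_HB replicate 4 (1.17) or HepaRG_Chol replicate 4 (1.03), AQP1 without HepaRG_HB replicate 4 (-1.05), ALB without HepaRG_HB replicate 2 (1.02), and HNF4A without HepaRG_HB replicate 1 (adjusted p = 6.4e-06) or HepaRG_Chol replicate 2 (1.05).

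The fourth comparison set HepaRG_Chol (4 arrays) against HepaRG_cHep (3 arrays), the cholangiocyte and hepatocyte routes at the same day of culture, 10. For this comparison, rose and fell mean higher and lower in HepaRG_Chol than in HepaRG_cHep, not a change in time. HepaRG_Chol had far lower levels of hepatocyte genes: SERPINC1, antithrombin, fell by 9.23 (SE 0.297), and TTR fell by 9.12 (SE 0.155). F12 was at least 190-fold lower and CYP8B1, an enzyme of bile acid synthesis, at least 98.6-fold lower. ALB was lower by 1.32 (SE 0.226) and AFP by 1.61 (SE 0.273). Against HepaRG_HB, with ALB at 7.03, ALB was not lower in HepaRG_Chol, at 7.82, and was higher by 2.11 in HepaRG_cHep. AFP was lower in HepaRG_Chol than in HepaRG_HB too, with -1.44. SPP1 and SLC4A2 rose by 1.52 (SE 0.261) and 1.42 (SE 0.245). KRT7 at -0.82 (SE 0.139), KRT19 at 0.91 (SE 0.182), SOX9 at 0.22 (SE 0.206), AQP1 at -0.90 (SE 0.225), GPBAR1 at -0.45 (SE 0.156), HNF4A at -0.88 (SE 0.173), CFTR and SCTR were not called.

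Of the plasma protein genes 20 fell and 5 were not called (adjusted p = 1.6e-16, but adjusted p = 0.0786 with an estimated correlation), and 21 fell when adjusted over the list alone. Of the drug metabolism genes 16 fell and 3 were not called (adjusted p = 3.5e-11, and adjusted p = 0.00201 with an estimated correlation), with UGT2B4 at -7.80 (SE 0.373) and CYP2C8 at -1.35 in HepaRG_cHep and above background on no HepaRG_Chol array. Of the amino acid and urea cycle enzymes 1 rose, 11 fell and 3 were not called (adjusted p = 9.7e-06, but adjusted p = 0.0786 with an estimated correlation), and 12 fell when adjusted over the list alone. ARG1 was at least 30.2-fold lower, and AGXT fell by 4.38 (SE 0.202). In the bile acid list 2 rose, 8 fell and 11 were not called (adjusted p = 0.00586, but adjusted p = 0.322 with an estimated correlation), with SLC27A5 at -5.37 (SE 0.220) and SLC10A1 at -4.72 (SE 0.232). Sugar metabolism (4 fell, 6 were not called, adjusted p = 0.00818) and inflammation genes (9 fell, 8 were not called, adjusted p = 0.00236, with SAA2 at -4.29 and ORM1 at -3.32) were called downward, with adjusted p = 0.251 and adjusted p = 0.428 with an estimated correlation. Cell cycle genes were called upward (13 rose, 10 were not called, adjusted p = 0.000268, but adjusted p = 0.549 with an estimated correlation), with TOP2A at 3.32 (SE 0.614) and RRM2 at 2.93 (SE 0.709). The HepaRG_cHep arrays disagreed here, with a median level of the list of 0.27 in replicate 1, -1.56 in replicate 2 and -1.41 in replicate 3, against 0.52 to 0.73 in HepaRG_Chol. The list was called upward without any one of them, with 20 risen members without replicate 1 but 6 without replicate 2 and 7 without replicate 3. Basement membrane and integrin genes were called upward too (10 rose, 1 fell, 7 were not called, adjusted p = 6.5e-06, but adjusted p = 0.0687 with an estimated correlation), with LAMB3 at 3.55 (SE 0.192) and ITGA2 at least 4.28-fold higher. Mesenchymal genes were called upward (8 rose, 1 fell, 13 were not called, adjusted p = 0.0461, but adjusted p = 0.193 with an estimated correlation), with S100A4 at 4.03 (SE 0.221) and SPARC at 2.52 (SE 0.138). That last list was not called after quantile normalization (adjusted p = 0.0928), median scaling (adjusted p = 0.0535) or with replicate number as a block (adjusted p = 0.0560). Of the biliary markers 6 rose, 0 fell and 14 were not called (adjusted p = 0.347), and of the liver transcription factors 5 fell and 10 were not called (adjusted p = 0.0752), with NR1I2 at -2.81 (SE 0.194). Except where given, counts adjusted over the list alone were the same for the lists named here.

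Of 17566 genes, limma called 3359 for HepaRG_Chol against HepaRG_cHep, 1660 higher and 1699 lower, and the largest rises were those of NIBAN1 with at least 25.0-fold, PDGFRL with 4.94 (SE 0.226), LEMD1 with at least 9.67-fold and NTS, above background on no HepaRG_cHep array and at a level of -1.72 in HepaRG_Chol. The share of called genes that were higher was 49.4%, or 63.6% after quantile normalization and 41.7% with normexp background. All HepaRG_Chol arrays were in scan 3 and all HepaRG_cHep arrays in scan 1, so batch and group cannot be told apart. Spike-in RNAs had a mean shift of -2.40 in HepaRG_Chol against HepaRG_cHep, with an SD of 0.652 over 10 probes. With normexp background the count was 1831, and ITGA2 (0.79) and NTS (adjusted p = 0.0508) were not called. ALB was not called after quantile normalization, with -0.61, or with all 28 files (adjusted p = 0.328). KRT19 was called after quantile normalization (1.22), after median scaling (adjusted p = 0.000117), with normexp background (adjusted p = 5.4e-05), with the authors' values (adjusted p = 0.000180), with array weights (1.04) and without HepaRG_cHep replicate 1 (1.15), and AQP1 without HepaRG_cHep replicate 3 (-1.05).

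**Figure D3:**
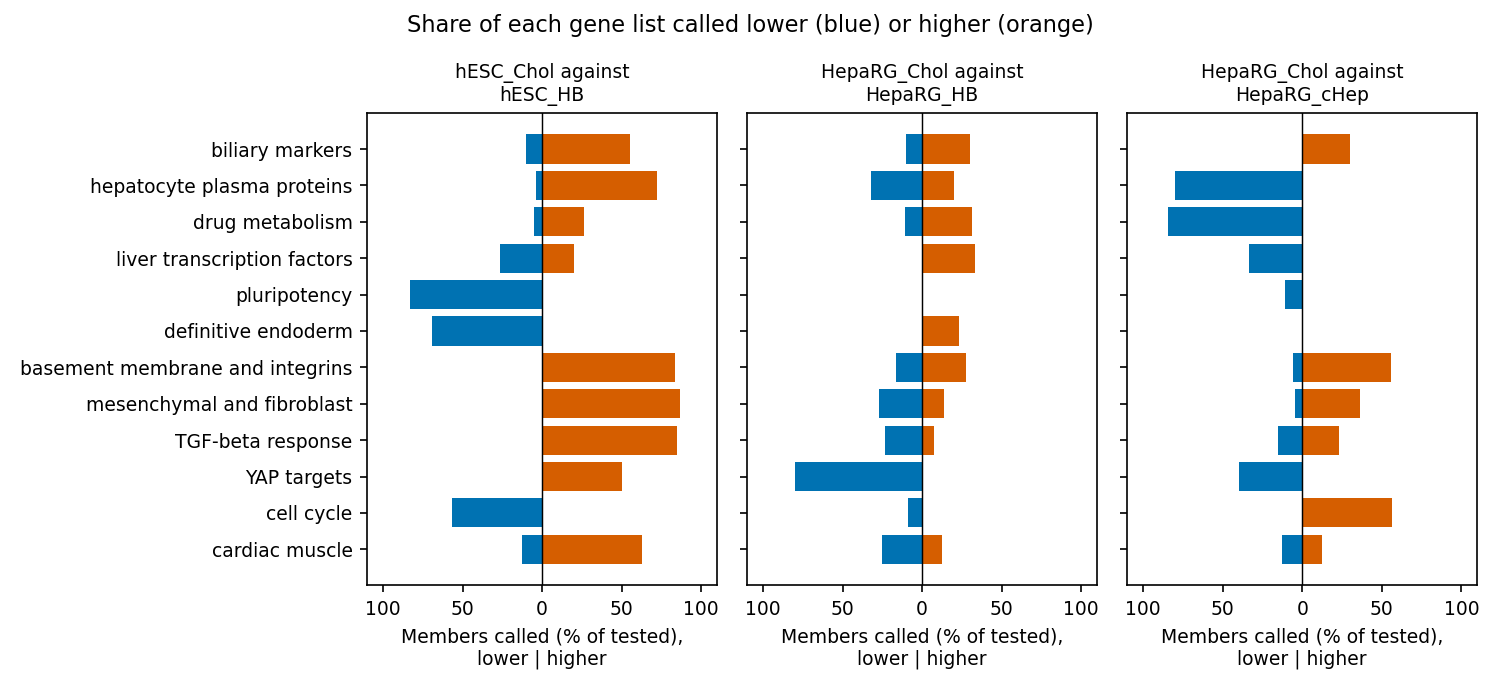
Share of the tested members of 12 gene lists that were called higher (right, orange) or lower (left, blue), in percent, for 3 comparisons. In hESC_Chol against hESC_HB 19 of 22 mesenchymal genes were called higher, in HepaRG_Chol against HepaRG_HB 8 of 10 YAP targets were called lower, and in HepaRG_Chol against HepaRG_cHep 16 of 19 drug metabolism genes were called lower.

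The hepatocyte route of HepaRG was compared at both of its stages with HepaRG_HB (4 arrays, day 4), as the counterpart of the cholangiocyte step. In HepaRG_Hep (3 arrays, day 30), CYP3A4, a main drug-oxidizing enzyme of liver, rose by 9.80 (SE 0.319), ARG1, the last enzyme of the urea cycle, to at least 462-fold and PLG to at least 477-fold. All 25 plasma protein genes rose in HepaRG_Hep, with APOC3 at 8.64 (SE 0.325), KNG1 at 8.61 (SE 0.573) and SERPINC1 at 8.37 (SE 0.297), and ALB rose by 2.51 (SE 0.226). In HepaRG_cHep (3 arrays, day 10) all 25 rose as well, with KNG1 at 6.18 (SE 0.573), SERPINC1 at 5.15 (SE 0.297) and TF at 4.30 (SE 0.298), and ALB rose by 2.11 (SE 0.226). All 23 cell cycle genes fell in HepaRG_Hep, with CDK1 at -3.66 (SE 0.477) and TOP2A at -3.57 (SE 0.614), and 19 of 23 fell in HepaRG_cHep, with CCNB1 at -2.19 (SE 0.362). The latter fall lay mostly in HepaRG_cHep replicates 2 and 3: 22 members fell without replicate 1 and 10 without replicate 2 or 3, and the list was called downward each time.

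In HepaRG_Hep SOX9 rose by 2.11 (SE 0.206), or 1.18 with normexp background, KRT19 fell by 1.23 (SE 0.182) and HNF4A was at least 3.05-fold higher, while KRT7, AQP1, GPBAR1, SLC4A2, SPP1, AFP, SCTR and CFTR were not called. In HepaRG_cHep SPP1 rose by 1.95 (SE 0.261) and HNF4A was at least 1.71-fold higher, while KRT7, KRT19, SOX9, AQP1, GPBAR1, SLC4A2, AFP, SCTR and CFTR were not called. CFTR was above background on no array of HepaRG_HB, HepaRG_Hep or HepaRG_cHep. The plasma protein list had adjusted p = 4.6e-24 in HepaRG_Hep and 5.5e-31 in HepaRG_cHep, and adjusted p = 0.0107 and 0.00498 with an estimated correlation. Of the drug metabolism genes 18 rose in HepaRG_Hep and 1 was not called (adjusted p = 1.8e-21, and adjusted p = 2.6e-05 with an estimated correlation), with ADH1B at least 284-fold higher. In HepaRG_cHep 14 rose and 5 were not called (adjusted p = 4.2e-20, and adjusted p = 4.2e-05 with an estimated correlation), with ADH1B at least 50.4-fold higher and ADH4 at 6.12 (SE 0.359), and 15 rose when adjusted over the list alone. The bile acid, transcription factor, amino acid and sugar lists were called upward in HepaRG_Hep with 15, 12, 12 and 9 members risen, and their calls held with an estimated correlation. Among these were CYP8B1 at 9.46, SLC27A5 at 8.73, NR1I3 at 6.31, NR1I2 at 4.89, AGXT at 8.81 and G6PC1 with at least 218-fold. The same lists were called upward in HepaRG_cHep with 12, 10, 11 and 7 members risen, also with an estimated correlation, with CYP8B1 at 6.04, NR1H4 at 3.29 and AGXT at 4.73, and 12 amino acid enzymes rose when adjusted over the list alone. The cell cycle list had adjusted p = 6.1e-11 in HepaRG_Hep and 3.4e-10 in HepaRG_cHep, but adjusted p = 0.157 and 0.184 with an estimated correlation. The mesenchymal list was called downward (12 of 22 fell in HepaRG_Hep, adjusted p = 2.7e-06, and 6 of 22 in HepaRG_cHep, where 16 were not called, adjusted p = 4.6e-05), and both calls held with an estimated correlation (adjusted p = 0.00161 and 0.00454). In HepaRG_Hep LUM fell by 5.38 (SE 0.249) and DCN fell by 4.00 (SE 0.237). TGF-beta response genes were called downward in HepaRG_Hep (1 rose, 6 of 13 fell, with TGFB2 at -4.13, adjusted p = 0.00797, but adjusted p = 0.0543 with an estimated correlation) and in HepaRG_cHep (1 rose, 4 of 13 fell, adjusted p = 0.000371, and adjusted p = 0.00931 with an estimated correlation). Basement membrane genes were called downward in HepaRG_Hep (1 rose, 9 of 18 fell, with COL4A1 at -2.56, adjusted p = 0.000146, but adjusted p = 0.0543 with an estimated correlation) and in HepaRG_cHep (0 rose, 5 of 18 fell, with COL4A1 at -2.44, adjusted p = 3.9e-05, and adjusted p = 0.0346 with an estimated correlation). The cholesterol list was called upward in HepaRG_Hep (7 rose, 10 were not called, adjusted p = 0.00506, but adjusted p = 0.316 with an estimated correlation). Epithelial junction genes were called upward and YAP targets downward in both, with 6 and 4 junction genes risen (adjusted p = 0.00949 and 0.0102) and 5 and 3 YAP targets fallen (adjusted p = 0.00176 and 0.000121). With an estimated correlation these had adjusted p = 0.255 and 0.261, and adjusted p = 0.152 and 0.0747. Intestinal genes were called upward in both (3 and 1 of 7, adjusted p = 0.0208 and 0.0479, but adjusted p = 0.103 and 0.159 with an estimated correlation), in HepaRG_cHep not with replicate number as a block (adjusted p = 0.0704). Inflammation genes were called upward in HepaRG_cHep (6 rose, 1 fell, adjusted p = 0.00242, but adjusted p = 0.321 with an estimated correlation), and 7 rose when adjusted over the list alone. Except where given, counts adjusted over the list alone were the same for the lists named here.

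Beside ADH1B, the largest rises in HepaRG_cHep included BDH1 with at least 34.0-fold. POSTN and AMTN were among the largest falls in both, with POSTN at -7.62 (SE 0.375) and -4.55 (SE 0.375), and AMTN at least 59.9-fold lower and at -4.62 (SE 0.186). The others were SPOCD1 with at least 134-fold and IGFL3 with -7.29 in HepaRG_Hep, and CNN1 with -4.86 and ODAPH with at least 7.12-fold in HepaRG_cHep. Limma called 3734 of 17566 genes for HepaRG_Hep against HepaRG_HB, 1803 higher and 1931 lower. It called 1747 for HepaRG_cHep against HepaRG_HB, 1000 higher and 747 lower. Within scan 1 the counts were 3919 and 1782, and with slide as a block 3626 and 1961. With normexp background the counts were 2220 and 907. With all 28 files they were 4149 (2658 of them shared) and 998. HNF4A was not called in either with normexp background (0.78 in HepaRG_Hep and 0.33 in HepaRG_cHep) or a floor of 0.05 (0.49 and 0.00), so its rise depends on the background, and CCNB1 in HepaRG_cHep was not called with the spread estimated from only the arrays compared (adjusted p = 0.0645). With all 28 files ALB was not called in HepaRG_Hep (adjusted p = 0.273) or HepaRG_cHep (adjusted p = 0.151). In HepaRG_Hep COL4A1 was then at -1.59 and KRT19 at -2.63. SCTR in HepaRG_Hep was called with replicate number as a block (1.05), with all 28 files (2.58) and without replicate 2 (1.30) or 4 (1.54). CFTR in HepaRG_Hep was called with the authors' values (-2.07), which include the column of HepaRG_Hep replicate 3. Leaving out single arrays called SLC4A2 in HepaRG_Hep without replicate 4 (-1.12) and KRT19 in HepaRG_cHep without replicate 1 (-1.10).

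The cholangiocyte steps of the cell lines were then compared directly by the difference of hESC_Chol against hESC_HB and HepaRG_Chol against HepaRG_HB. Their starting groups were unlike. POU5F1 lay at 6.57 in hESC_HB and from -1.33 to -0.26 in HepaRG_HB, and the means of ALB were -5.89 and 7.03. The steps are thus not like for like, and the part of the starting groups in their difference was not separated. UBD with 13.11 (SE 0.366), AFP with 11.47 (SE 0.340) and H19 with 10.84 (SE 0.487) were among the largest differences toward hESC_Chol, and PTPRZ1 with -9.60 (SE 0.564) and ACP3 with -9.34 (SE 0.642) among the largest in the other direction. ODAPH and CGA toward hESC_Chol and ESRG and ETNPPL in the other direction were also among them, but were above background on no array of 1 or more groups, so no size is given here. The size and rank of a difference from a dim group depend on the floor, and with a floor of 0.05 it was -6.21 for PTPRZ1 and -5.62 for ACP3. Mesenchymal genes had 18 higher differences of 22 (adjusted p = 8.5e-11, and adjusted p = 3.7e-05 with an estimated correlation), TGF-beta response genes 11 of 13 (adjusted p = 3.8e-08, and adjusted p = 0.000346 with an estimated correlation) and YAP targets 9 of 10 (adjusted p = 6.0e-05, but adjusted p = 0.0885 with an estimated correlation). Of the biliary markers 10 were higher, 2 lower and 8 not called (adjusted p = 0.0358, but adjusted p = 0.190 with an estimated correlation, and adjusted p = 0.05003 with the authors' values). Counts adjusted over the list alone were the same for these 4 lists.

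Over 17566 genes the 2 sets of log2 fold changes had a Pearson r of -0.0857 and a Spearman rho of -0.0901, across genes, which are not independent replicates. Over the 6853 genes called in either r was -0.0947. With normexp background r was -0.0269. Called genes that rose in both numbered 305 against 216 expected from the counts, and those that fell in both 162 against 219. Genes up in hESC_Chol and down in HepaRG_Chol numbered 284 against 183, and those down in hESC_Chol and up in HepaRG_Chol 483 against 258. Limma called 6966 genes for the difference, 3291 higher and 3675 lower. The HepaRG step lies between scans, so for that part of the difference batch and group cannot be told apart. The unlike starting groups also enter the correlations and these counts.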

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

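The tests of technical explanations in this part were chosen only after the results were seen, except for the splits of the arrays and the comparison of scans within HepaRG_HB. The difference of the cholangiocyte steps and its list tests were planned.

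The first pattern is the set of genes that differed between HepaRG_Chol, all in scan 3, and the other HepaRG groups, none of which were. A scan effect as the whole cause of both differences at once is argued against by the 1782 genes called between HepaRG_cHep and HepaRG_HB within scan 1. That count was foreseeable from the 1747 genes of the main fit, and it compares no HepaRG_Chol array. It therefore cannot decide whether scan is the whole cause of either difference alone. A part of the cause in the scan cannot be told apart from the groups: the shift of the spike-in RNAs in HepaRG_Chol against HepaRG_HB had an SD of 0.679 over all 10 probes and 0.376 over the 7 brighter ones, a restriction tried after the first value was seen, and neither excludes a batch part. HepaRG_HB replicate 4, in scan 2, lay over 1 log2 from the mean of replicates 1 to 3, in scan 1, in 1642 genes, between the bounds set for either reading against 3059 called genes. No such count was made for a replicate within scan 1, and scan 3 does not enter it, so it cannot decide on scan. Over probes, the median correlation of replicate 4 with its group was 0.957. It was 0.957 for replicate 1, 0.949 for replicate 2 and 0.967 for replicate 3. The difference in differentiation route stays open beside the scan, as untested.

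The second pattern is the rise of mesenchymal and cardiac genes in hESC_Chol, markers of cell types other than cholangiocytes. For RNA of mouse feeder cells, on which the hESC were kept, levels in hESC_Chol were set against those in hESC. They were higher in hESC_Chol, with a median of 3.11 over the 22 mesenchymal genes, 20 of them above 1, and 4.11 over the 8 cardiac genes, 6 of them above 1. This bears on feeder RNA only if the hESC arrays held at least as much of it as hESC_Chol. Feeder RNA was measured in no group, so the comparison cannot decide. For the mesenchymal genes, scaling and slide are argued against as whole causes, since the lowest median change of the list was 3.29 over quantile normalization, median scaling, normexp background and the authors' values, and 3.63 within slides 5 and 6, the latter with 1 hESC_Chol array. Such medians were not taken for the cardiac genes. A candidate explanation is that mesenchymal and cardiac cells formed in the same cultures, or that the cholangiocyte-like cells expressed these genes themselves. Bulk arrays give no value that parts these, and both stay open.

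The third pattern is hESC replicate 1, which differed from replicates 2 and 3 by over 1 log2 in 5118 and 4417 genes, while replicates 2 and 3 differed in 590. Slide is argued against as the cause, since replicates 1 and 2 with their 5118 genes lay on one slide. For a failed array the measure set was the share of spots well above background, 72.2% on replicate 1 against 70.8% and 75.8%. That share cannot decide, since the failed array of HepaRG_Hep had 91.5%. A failure of that kind is argued against by replicate 1's good grid, spike-in slope of 1.02, 0 saturated spots and 413 outlier spots. A swap with an hESC_HB array is argued against by a lowest correlation over genes of 0.994 among the 5 hESC_HB arrays. Replicates 2 and 3 had SOX17 at 2.19 and 1.86, EOMES at 0.88 and 0.40, and ZFP42 at -5.59 and -5.79, where replicate 1 had SOX17 and EOMES at the floor and ZFP42 at 4.54. A difference in the state of the cultures, and a wrong label or a sample from outside the series, stay open.

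Other splits of the same arrays gave fewer genes than the real split, which alone (1 split) reached its count in each comparison. Splits that mix the groups also widen the estimated spread, which lowers their counts by construction. With as few as 35 splits the test therefore does not exclude chance by itself, and it cannot separate group from scan. For hESC_HB against hESC the real split gave 2501 and the highest other of 56 splits 1045. The values were 5028 and 2199 of 100 splits for hESC_Chol against hESC_HB, 3059 and 835 of 35 for HepaRG_Chol against HepaRG_HB, and 3359 and 1819 of 35 for HepaRG_Chol against HepaRG_cHep. They were 3734 and 2726 of 35 for HepaRG_Hep against HepaRG_HB, 1747 and 1087 of 35 for HepaRG_cHep against HepaRG_HB, and 6966 and 2 of 100 for the difference of the cholangiocyte steps.

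One array stood apart from the others of its group in 23 of 241 groups of values, by the gap to the nearest array as a share of the group's range, where chance gives about 1 in 20. In HepaRG_Chol replicate 4 stood apart for ADH4 (gap 0.947), CLDN4 (0.931), ELF3 (0.871), FOXA1 (0.944), ORM1 (0.838) and POSTN (0.865), and replicate 1 for GPBAR1 (0.835) and RGS4 (0.900). In hESC_HB it was replicate 2 for AFP (0.723), ALAS2 (0.758), CCL2 (0.784), DLL1 (0.762) and H19 (0.719), replicate 4 for HES1 (0.909) and replicate 1 for SOX17 (0.859). In hESC_Chol it was replicate 5 for COL3A1 (0.803), PLK1 (0.719), SERPINA1 (0.866) and SLC4A2 (0.823), replicate 4 for GSC (0.772) and NPPA (0.742), and replicate 1 for FGB (0.742). In HepaRG_HB it was replicate 4 for SOX9 (0.842). Since the gap is a share of the range, it can be small in size where replicates are tight. ALAS2 lay at 2.80 on the array apart against a mean of 2.91 on the others, and COL3A1 at 2.35 against 2.44. RGS4 lay at -0.36 against -1.92, and H19 at -2.89 against -1.60.

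The cholangiocyte steps of the cell lines, which began from unlike starting groups, differed in 6966 genes by the test of the difference itself. As fitted with the floor of 0.01, the log2 difference was 13.11 for UBD, 11.47 for AFP, 10.91 for ODAPH, 10.85 for CGA, 10.84 for H19, -11.76 for ESRG, -9.71 for ETNPPL, -9.60 for PTPRZ1 and -9.34 for ACP3. CGA, ESRG, ODAPH and ETNPPL were above background on no array of 1 or more groups, so their sizes and ranks are set by the floor and are not measured changes: with a floor of 0.05 the difference was 6.62 for ODAPH, -6.21 for PTPRZ1 and -5.62 for ACP3. Among marker genes it was 3.38 for KRT7, 3.49 for SOX9, 4.20 for AQP1, 7.57 for ALB and -1.24 for HNF4A, which was above background on no HepaRG_HB array, so that this last size also depends on the floor. The size for AQP1 holds for its main probe, whose change in hESC_Chol against hESC_HB was 3.37, against 6.07 with the mean of its probes. The median difference was 1.04 for the biliary list, 4.16 for plasma proteins, -2.87 for pluripotency, -3.37 for definitive endoderm, 2.43 for basement membrane, 4.39 for mesenchymal, 3.58 for TGF-beta response, 2.80 for YAP targets, 1.76 for inflammation, -1.10 for hypoxia and 3.86 for cardiac genes. With an estimated correlation the lists of biliary markers, plasma proteins, definitive endoderm, YAP targets, inflammation and hypoxia were not called (adjusted p = 0.190, 0.190, 0.495, 0.0885, 0.233 and 0.205).

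Transcripts without a gene name, which the comparisons of genes leave out, also differed: 1738 of 11517 were called for hESC_Chol against hESC_HB, 526 higher and 1212 lower, and 2522 for HepaRG_Chol against HepaRG_HB, 460 higher and 2062 lower. In HepaRG_Chol against HepaRG_cHep 388 were higher and 2442 lower, while in HepaRG_Hep against HepaRG_HB 972 were higher and 518 lower. Both HepaRG_Chol comparisons lie between scans, so batch and group cannot be told apart for this lean either.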

How the results depend on the processing

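The alternatives with all 28 files, a floor of 0.05, transcripts without a gene name, single slides or scans, the lists without hESC replicate 1 and the cell cycle list without each HepaRG_cHep array were chosen after the data were seen. Of 7054 values of named genes under alternatives, 6987 kept their side of the threshold, and called ones also their direction, 32 lost the call, 35 gained it and 0 reversed; of 1653 list values 1523 did so, 54 lost the call, 76 gained it and 0 reversed. The direction of values not called in either was not compared.

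In the order hESC_HB against hESC, hESC_Chol against hESC_HB, HepaRG_Chol against HepaRG_HB, HepaRG_Chol against HepaRG_cHep, HepaRG_Hep and HepaRG_cHep against HepaRG_HB, and the difference of the cholangiocyte steps, dropping the minimum fold gave 6304, 10475, 8025, 8015, 7759, 4353 and 10496 genes, since a call then needed the adjusted p alone. With normexp background the counts were 1487, 1647, 1831, 2220 and 907 for hESC_HB against hESC, HepaRG_Chol against HepaRG_HB and HepaRG_cHep, and HepaRG_Hep and HepaRG_cHep against HepaRG_HB, and the correlation of the cholangiocyte steps was -0.0269; the cause was not tested. That setting moved the median of all genes to -0.24, -0.21 and 0.14 for HepaRG_Chol against HepaRG_HB and HepaRG_cHep and for HepaRG_Hep against HepaRG_HB, and to 0.18 for the difference of the steps. All 28 files gave 1561 genes for hESC_HB against hESC and 998 for HepaRG_cHep against HepaRG_HB, neither of which holds the added array. Including transcripts without a gene name, which adds features to test, gave 5580, 6182 and 10834 for HepaRG_Chol against HepaRG_HB and HepaRG_cHep and for the difference. Of 72 list calls, 29 held with an estimated correlation, and fry, which compares no list with other genes, called 136. Calls gained with normexp background were those of epithelial junctions for hESC_HB against hESC (adjusted p = 0.0180), interferon and pancreatic genes for HepaRG_Chol against HepaRG_cHep (adjusted p = 0.0165 and 0.0154), and cell cycle and pancreatic genes for the difference of the steps (adjusted p = 0.0130 and 0.0185), beside basement membrane and interferon genes for HepaRG_Chol against HepaRG_HB (adjusted p = 0.0279 for both). For the difference, pancreatic genes (adjusted p = 0.0403) and interferon genes (adjusted p = 0.0438) were also called after quantile normalization, and interferon genes with the authors' values (adjusted p = 0.0353). Scan 2 holds 1 array of HepaRG_HB and 1 of HepaRG_Hep, so no comparison within it is given.

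Leaving out 1 array at a time gave 2378 to 3223, 4971 to 5034, 2767 to 3569, 3050 to 3483, 3533 to 4064, 1511 to 2009 and 6750 to 7264 genes in the order above, and correlations from -0.0948 to -0.0725. For HepaRG_Chol the slide could enter only as a random block, which gave 3035 and 3290 genes against HepaRG_HB and HepaRG_cHep and 6930 for the difference. Signal over background is the limit on depth: a floor of 0.05 gave 1831, 4022, 2311, 2525, 2995, 1335 and 5827 genes, and the size of a change from a dim group depends on it.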

Other observations

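The tests in this part are the fixed gene lists, with members named here chosen after their values were seen. In HepaRG_Chol against HepaRG_HB, the lists of other cell types were not called: endothelial (1 rose, 2 fell, adjusted p = 0.764), cardiac (1 rose, 2 fell, adjusted p = 0.620), neural (0 rose, 1 fell, adjusted p = 0.991), intestinal (2 rose, 1 fell, adjusted p = 0.948), pancreatic (0 rose, 0 fell, adjusted p = 0.525) and blood cells (1 rose, 0 fell, adjusted p = 0.560). Interferon genes (4 rose, 0 fell, adjusted p = 0.329) and TGF-beta response genes (1 rose, 3 fell, adjusted p = 0.355) were not called either, though with normexp background the interferon list was called upward (adjusted p = 0.0279). Counts adjusted over the list alone were the same for these 8 lists.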
